A study of Mus musculus with 6 samples.

How the data were processed

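Gene expression was measured on 6 Affymetrix GeneChip Mouse Gene 2.0 ST arrays, 3 from wild-type (WT) mice and 3 from Merit40-/- mice. The RNA came from freshly isolated hematopoietic stem cells (HSCs) of the bone marrow of young adult mice, double sorted as CD150+CD48- cells of the lineage-negative, Sca-1+, c-Kit+ (LSK) gate, per the labels. Per the labels' protocols, total RNA was extracted with the miRNeasy kit and 50 ng of it was amplified and biotin-labelled with the NuGEN Pico kit. The labels number the arrays as biological replicates 1 to 3 of each genotype. They do not say how many mice went into each array, so the p-values below measure the spread between these arrays.

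The deposited values are log2 expression values, 1 per probe set and array, which the authors made with RMA and the affy package, per the submitters' processing notes. RMA corrects the background of the probes, gives all arrays the same distribution of intensities and combines the probes of a probe set. Versions, the chip definition and the genome build are not given in the sources used here. The probe sets are named by NCBI Entrez Gene number, so each gene has 1 probe set. RMA removes any overall difference in RNA yield between arrays, and its log2 values compress the differences of genes near the array background. Levels of different probe sets are therefore not compared as amounts of transcript, and the median over all genes serves only as a mark of low signal. The scanner intensities were not analysed here.

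The table held 25206 probe sets, 6 arrays and 0 missing values. Of these probe sets, 23185 had exactly 1 gene symbol, 0 had several and 2021 were unnamed here. The Entrez numbers of all 23185 were found in the reference gene table (assembly GRCm38.p6), which was used only for current symbols and for the order of genes along a chromosome. The 23185 named genes were tested without a filter on level.

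Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the only term, 2-sided) with Benjamini-Hochberg adjustment over the 23185 genes and a threshold of 0.05 on the adjusted p. Differences are Merit40-/- minus WT on the log2 scale, with limma's moderated standard error (SE). Group levels are means with SD over 3 arrays. The Babam1 level was also compared with an exact permutation test. Gene lists were compared with camera from limma at its preset correlation of 0.01, adjusted over the 27 lists with at least 5 measured members, and again with an estimated correlation and with fry. The lists held 808 genes, of which 740 were measured, and 3 older symbols were updated. The shift of a list is the mean difference of its members, and its SE is that of the group means of the list between arrays. The 50 nearest named genes on each side of Babam1 were tested as a further list.

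The genes named in the text follow a rule fixed before the data were examined, as were the tests, the lists and the alternatives. It takes Babam1, up to 12 genes per direction and, for each list, members past the threshold or else the members with the highest and lowest difference. The 12 genes per direction are those past the adjusted threshold, with at least 1 group mean at or above the median of all genes and no overlap between the arrays of the 2 genotypes. Free places are filled by smallest unadjusted p among such genes with a difference of at least 0.58 (1.49-fold). Predicted loci, small RNAs, chemosensory receptors and the genes of a fixed sex-linked list (such as Xist and Kdm5d) are left out. Further genes named in the text, among them the skeletal muscle genes, G530011O06Rik, Mid1, Ctsk and Acp5 and further members of the lists, were chosen after their values were seen. The member with the highest difference in the recombination and Fanconi anaemia list is not reported here. Likewise, the 30 muscle genes and 14 osteoclast genes used as markers were listed after single arrays had been seen to stand apart, but before the values of these markers were looked at.

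Simulated values were drawn with the means of these arrays and independent normal noise at limma's moderated variance of each gene. The procedure was tested on these values, with 200 of the 23185 genes changed. It called 12.5% of the genes changed by 0.58 (10 of 80), 85.2% of those changed by 1 (46 of 54) and 100% of those changed by 2 (66 of 66), with 7 unchanged genes called. These shares hold for 200 changed genes. With fewer changed genes the adjustment is stricter, so the shares overstate what can be called where few genes change. Moderated variances are also more alike between genes than the observed ones, so the shares overstate the calls for genes with scattered arrays. In the data, Lrmda at -2.38 and G530011O06Rik at -2.25 did not pass. The alternatives were a replicate block, another variance model, array weights, 3 further scalings, 2 filters on dim genes, each array left out in turn, an unmoderated test per gene, other thresholds, and 25 or 100 neighbours on each side of Babam1.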

Results

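Merit40, encoded by Babam1, is a shared subunit of the BRISC and BRCA1-A complexes, in which the deubiquitinase Brcc3 cleaves lysine-63-linked ubiquitin chains. The data compare the transcriptome of sorted bone marrow HSCs from Merit40-/- mice with that of WT mice, with 3 arrays per genotype. The comparison asks what the loss of this subunit does to gene expression in freshly isolated HSCs. Each array held 25206 probe sets, with medians of 4.91 to 4.97 and highest values of 13.1 to 13.2 on the log2 scale. Over all probe sets, Pearson's r was 0.987 to 0.988 within WT, 0.984 to 0.985 within Merit40-/- and 0.985 to 0.988 between genotypes. These correlations are across genes, which are not independent replicates. The number of arrays limits the precision: the median gene had a 95% interval of ±0.342 around its difference.

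Babam1 (Entrez Gene 68251) was lower in all 3 Merit40-/- arrays. It read 7.91, 8.04 and 8.05 on the WT arrays and 4.29, 3.87 and 4.01 on the Merit40-/- arrays. Its level was 8.0 ± 0.08 (SD, n = 3) in WT and 4.06 ± 0.21 (SD, n = 3) in Merit40-/- HSCs. The gene fell by 3.94 (SE 0.14), or 15.4-fold as read on the array, with an adjusted p of 5.04e-05 in limma. The Merit40-/- level lies below the median level of all genes (4.93), where log2 values are compressed, so the fold is not an exact measure of the remaining transcript. An exact 2-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow. The sex of the mice is not given in the labels. The Y-linked gene Kdm5d stood at 2.81 in WT and 3.00 in Merit40-/-, and Xist, expressed from the inactive X chromosome, at 11.54 and 11.51. In both genotypes Kdm5d thus lay below the median of all genes and Xist far above it, which is the pattern of female cells.

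A set of skeletal muscle genes stood apart in 1 array, Merit40-/- replicate 1. Acta1, the actin of skeletal muscle fibres, read 10.42 there against 5.34 to 6.35 on the other 5 arrays. The fast troponin genes Tnnt3 and Tnnc2 read 10.39 and 10.26, against at most 6.38 and 5.88 elsewhere, and the muscle calcium buffer Pvalb read 9.35 against at most 4.74. In this array 18 genes lay at least 2 log2 units above each of the other 5 arrays, compared with 0 to 5 genes in any other array. Not all 18 are muscle genes, as they include the immunoglobulin gene segments Ighv14-2 and Igkv5-39 and the microRNA gene Mir3097. None of the fixed lists holds any of these 18 genes. Of the 34 genes at least 2-fold higher in the Merit40-/- mean, 11 belong to these 18. In Merit40-/- replicate 3, the osteoclast protease Ctsk read 7.94 against at most 3.89 elsewhere, and the osteoclast phosphatase Acp5 read 7.91 against at most 5.19.

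**Figure D1:**
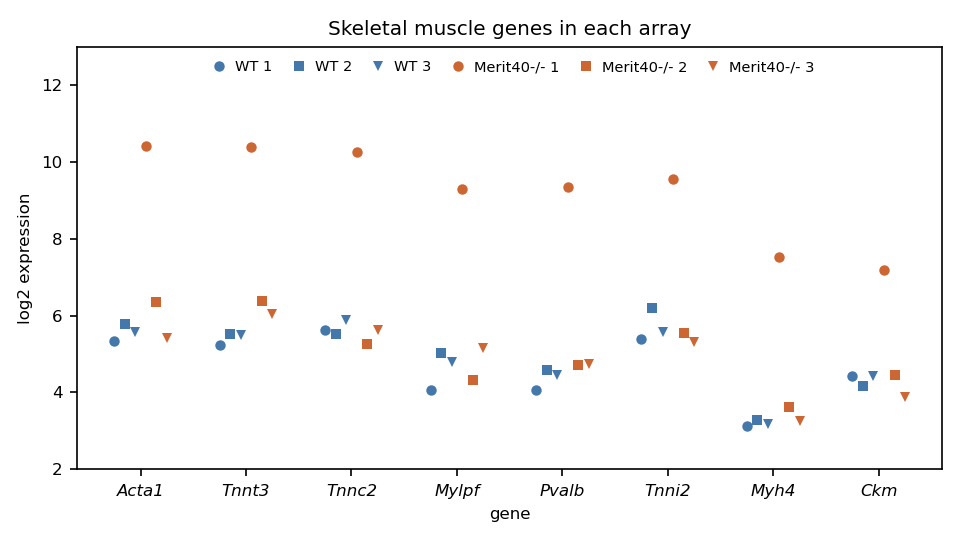
Log2 expression (vertical axis) of 8 skeletal muscle genes (horizontal axis) on each array, with WT arrays in blue, Merit40-/- arrays in orange and 1 symbol shape per replicate number. Merit40-/- replicate 1 lies above the other 5 arrays for each of the 8 genes, from 2.74 log2 units for Ckm to 4.62 for Pvalb.

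Babam1 was the only gene to pass the threshold in limma: 1 of 23185 genes fell and 0 rose at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 979 genes (4.22%), where chance alone gives 1159. The smallest adjusted p after Babam1 was 0.136 in limma, for G530011O06Rik, an uncharacterised transcript at 7.56 ± 0.36 (SD, n = 3) in WT and 5.31 ± 0.38 (SD, n = 3) in Merit40-/-. For 22339 genes (96.4%) the 95% interval of the difference lay within 2-fold in either direction. This count includes genes of low signal, whose log2 differences are compressed, so a 2-fold change in their transcripts is not excluded. An unmoderated per-gene test called 0 genes, with Babam1 at the smallest adjusted p of 0.168 and 990 genes at an unadjusted p under 0.05. The arrays of the genotypes did not overlap for 2099 genes (9.05%), where chance gives 10%.

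Among the genes lower in Merit40-/- without passing the threshold, Slc35d3, a solute carrier gene linked to platelet dense granules, stood at 6.65 in WT and 5.77 in Merit40-/-. Its difference was -0.89 (adjusted p = 0.553 in limma). Pcbp4, a poly(C)-binding protein, differed by -0.83 at the same adjusted p in limma. Lrmda, a leucine-rich repeat gene of melanocyte differentiation, differed by -2.38 (5.22-fold), but its arrays were scattered at 7.40 ± 0.70 (SD, n = 3) in WT and 5.01 ± 0.76 (SD, n = 3) in Merit40-/-. Erdr1, an erythroid differentiation regulator, read 12.04 in WT and 10.84 in Merit40-/- (2.30-fold). The histone H2A gene H2aw differed by -1.02, the transcriptional corepressor Cir1 by -0.91, the myeloid receptor Cd300ld3 by -0.90, Gemin8 of the SMN complex by -0.84, Mccc1os by -0.67, the glycosyltransferase Alg12 by -0.63 and Sac3d1 by -0.61.

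Among the genes higher in Merit40-/-, none past the threshold, the neuregulin Nrg4 read 6.25 in WT and 7.09 in Merit40-/- (difference 0.84, adjusted p = 0.644 in limma). The lipocalin Lcn12 differed by 0.82 and Traf3ip2, the adaptor of interleukin-17 receptors, by 0.74, both at that same adjusted p in limma. The tumour necrosis factor family ligand Tnfsf13 read 4.74 and 6.13, and the immune receptor Pilrb1 3.78 and 5.14. The adhesion receptor Adgrg2 differed by 0.73, the small heat shock protein Cryab by 0.72, the thiopurine methyltransferase Tpmt by 0.71, the apoptosis inhibitor Faim by 0.71, Habp4 by 0.68, Znhit2 by 0.68 and the ubiquitin-conjugating enzyme Ube2h by 0.60.

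**Figure D2:**
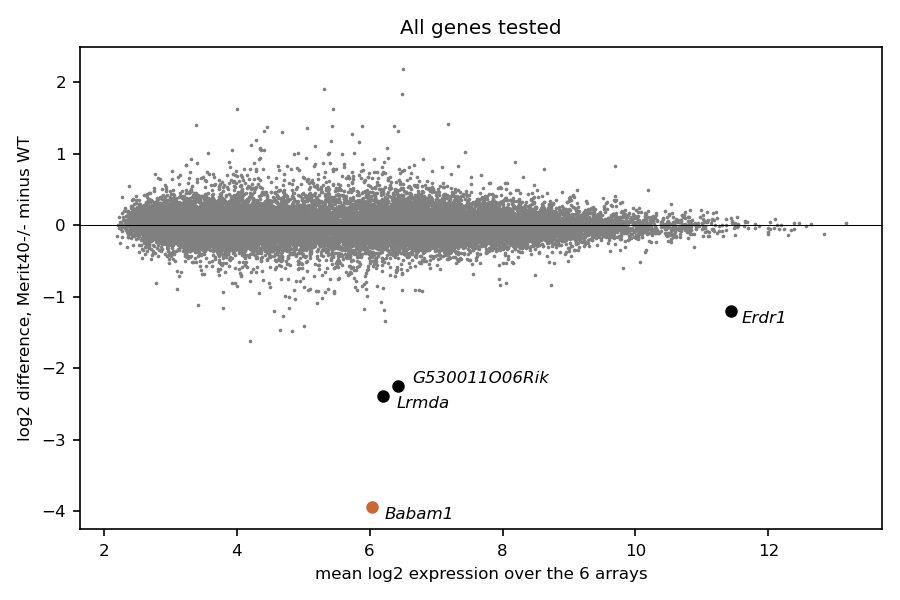
Log2 difference between Merit40-/- and WT (vertical axis) against the mean log2 expression over the 6 arrays (horizontal axis), 1 grey point for each of 23185 genes. Babam1 (orange) lies at -3.94 and is the only gene past an adjusted p of 0.05 in limma, and Lrmda, G530011O06Rik and Erdr1 (black) did not pass it.

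**Figure D3:**
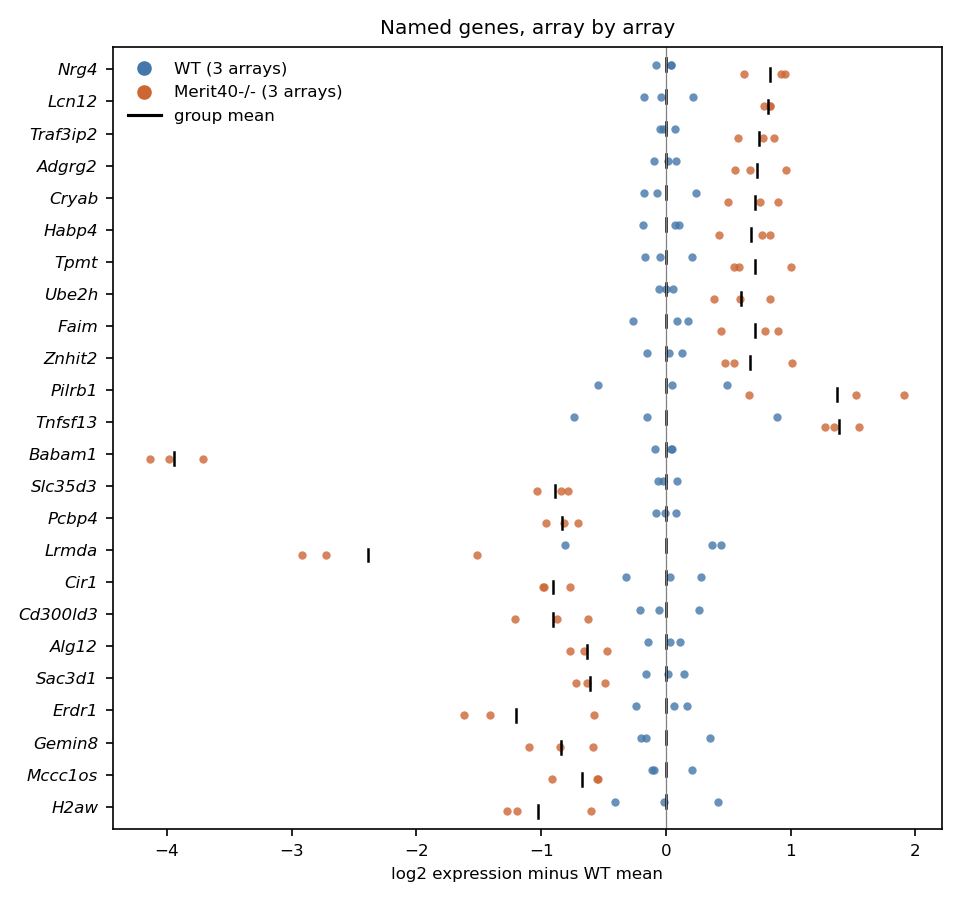
Log2 expression of the genes named by rule, as the difference from the WT mean of each gene (horizontal axis), with WT arrays in blue, Merit40-/- arrays in orange and group means as black bars. Babam1 reaches -3.94, and the arrays of the 2 genotypes do not overlap for these genes, which is one of the conditions by which they were chosen.

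Apart from Babam1, no gene of the BRISC and BRCA1-A complexes passed the test, with differences from -0.25 to 0.32. Of the 9 measured genes, 1 passed the threshold, Babam1 itself, and 1 passed adjusted over the list alone. The scaffold gene Babam2 differed by 0.27 (SE 0.13), Abraxas2 of BRISC by 0.32 (SE 0.16) and Abraxas1 of BRCA1-A by -0.25 (SE 0.12). The deubiquitinase gene Brcc3 differed by -0.14 (SE 0.15), Brca1 by -0.04 (SE 0.16), Bard1 by -0.11, Uimc1 by 0.02 and Shmt2 by -0.10. The list as a whole had an adjusted p of 0.123 with camera from limma. It passed with fry at an adjusted p of 0.0105 in limma, and without Merit40-/- replicate 3 with camera at an adjusted p of 0.0356 in limma (all arrays: adjusted p = 0.604 with an estimated correlation). The 8 genes other than Babam1 averaged -0.0050, at adjusted p values of 0.937 with camera and 0.961 with fry in limma, so the fry call over all arrays rests on the deleted gene.

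Lists of cell division and DNA repair genes passed the test only at the preset correlation of camera, and the array means of the genotypes overlapped in each of them. In the mitosis and G2/M list, 36 of 39 members were lower and 3 higher, with a mean difference of -0.22 (SE 0.13 between arrays), and the list fell relative to the other genes in camera from limma (adjusted p = 3.03e-09). That call was lost when the correlation was estimated (adjusted p = 0.630 with an estimated correlation of 0.471). The proliferation marker Mki67 differed by -0.29 (SE 0.17), the topoisomerase Top2a by -0.21 (SE 0.16), the spindle protein Dlgap5 by -0.48 (SE 0.25) and Racgap1, of cytokinesis, by 0.09 (SE 0.17). Relative to the WT mean, the list averaged -0.34, 0.02 and -0.35 in Merit40-/- replicates 1, 2 and 3, so that the low values came from the array with muscle genes and the array with high Ctsk and Acp5. Its exact permutation p over the list means of the arrays was 0.2. In the list of DNA replication and G1/S genes, 29 of 37 members were lower, with a mean of -0.11 (SE 0.13), and the list fell in camera from limma (adjusted p = 0.0166, and adjusted p = 0.776 with an estimated correlation). Its replication factor Cdc45 differed by -0.46 and the clamp loader gene Rfc3 by 0.21. The homologous recombination and Fanconi anaemia list had 29 of 36 members lower, with a mean of -0.11 (SE 0.05), and fell in camera from limma (adjusted p = 0.00628, and adjusted p = 0.604 with an estimated correlation). Fancg of the Fanconi core complex differed by -0.49 (SE 0.15), and 7 members were higher in Merit40-/-. In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone.

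With each array left out in turn, the mitosis list stayed past the threshold in camera at the preset correlation, at means of -0.34 to -0.16. With all arrays it did not pass in camera with an estimated correlation (adjusted p = 0.630). The replication list lost its call without WT replicate 1 (-0.07), WT replicate 2 (-0.08) or Merit40-/- replicate 1, the array with muscle genes (-0.0087), and the recombination list without the same arrays, at -0.08, -0.10 and -0.10.

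The erythroid and megakaryocyte lists also passed only at the preset correlation of camera, with overlapping array means. Of 24 erythroid genes, 20 were lower and 4 higher, with a mean of -0.20 (SE 0.15 between arrays), and the list fell in camera from limma (adjusted p = 0.00270, and adjusted p = 0.604 with an estimated correlation). The erythroid surface protein gene Ermap stood at 5.31 in WT and 4.41 in Merit40-/- (difference -0.90, SE 0.32), the carbonic anhydrase Car1 at 8.38 and 7.54, and the transcription factor gene Gata1 at 7.50 and 7.13, while Rhag of the red cell membrane differed by 0.43 (SE 0.30). Of 29 megakaryocyte and platelet genes, 20 were lower and 9 higher, with a mean of -0.12 (SE 0.05), and the list fell in camera from limma (adjusted p = 0.0221, and adjusted p = 0.604 with an estimated correlation). The integrin gene Itga2b stood at 8.42 and 7.90 (difference -0.53, SE 0.13), the platelet chemokine gene Pf4 at 10.12 and 9.52, and Ppbp differed by -0.68 (SE 0.39), while Vwf differed by 0.14 (SE 0.20) and Thbs1 by 0.63 (SE 0.60). In both lists 0 members passed over all genes and 0 adjusted over the list alone. The estimated correlation of the megakaryocyte list, 0.006, lies below the preset 0.01, so correlation between its members does not account for its lost call. Its unadjusted p in camera still rose from 0.00409 to 0.0398 with the estimated correlation. Both settings of camera therefore differ in more than the correlation, and a call lost between them does not by itself show correlated members. The erythroid list lost its call without WT replicate 1 (-0.08) or without Merit40-/- replicate 1, the array with muscle genes (-0.16), and the megakaryocyte list without WT replicate 1, WT replicate 2, Merit40-/- replicate 1 or Merit40-/- replicate 2 (-0.11 to -0.097), and also without the dimmest 30% of genes (adjusted p = 0.0508 in limma).

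Markers of HSC identity and thrombopoietin signalling genes did not pass the test as lists. Of 31 long-term HSC genes, 22 were higher and 9 lower, with a mean of 0.08 (adjusted p = 0.0756 with camera from limma). The sorting marker gene Slamf1 (CD150) differed by 0.18 (SE 0.22), Kit by 0.09 (SE 0.11), Procr by -0.06 (SE 0.18), Robo4 by 0.31 (SE 0.21) and Gfi1 by -0.24 (SE 0.13). This list rose past the threshold in camera from limma without WT replicate 3 (mean 0.13) or without Merit40-/- replicate 3 (mean 0.12), and averaged 0.02 without Merit40-/- replicate 1, the array with muscle genes. With all arrays it had adjusted p = 0.776 with an estimated correlation in limma. The JAK2-STAT5 signalling components had 13 of 22 members higher, with a mean of 0.07 (adjusted p = 0.247 in camera from limma). Sh2b3, which encodes the adaptor Lnk that restrains thrombopoietin signalling through JAK2, stood at 7.50 in WT and 8.09 in Merit40-/- (difference 0.59, SE 0.15), with an adjusted p of 0.999 over all genes and of 0.101 adjusted over the list alone in limma. Jak2 differed by -0.06 (SE 0.14), Stat5a by -0.01 (SE 0.12), Stat5b by -0.21 (SE 0.18) and Crkl by -0.23 (SE 0.14). The STAT5 target genes had a mean of 0.05 over 23 members (adjusted p = 0.564 in camera from limma), with Cish at 0.10 (SE 0.21), Pim1 at 0.06 (SE 0.27), the cell cycle inhibitor gene Cdkn1a at 0.78 (SE 0.22) and Id1 at -0.35 (SE 0.18). Quiescence genes and CDK inhibitors, which include Cdkn1a, averaged 0.08 over 24 members (adjusted p = 0.247 in camera from limma), with the antiproliferative gene Btg2 as their lowest member at -0.58 (SE 0.23). Without Merit40-/- replicate 1, the array with muscle genes, the signalling components averaged 0.03 and the STAT5 targets 0.02, and without WT replicate 1 they averaged 0.04 and 0.03. Without the dimmest 50% of genes the STAT5 targets averaged 0.11 (adjusted p = 0.134 in camera from limma). In these 4 lists 0 members passed over all genes and 0 adjusted over the list alone.

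Markers of other blood lineages and of other cells of the marrow did not pass the test as lists. The 29 granulocyte and monocyte genes averaged 0.07 (SE 0.18 between arrays, adjusted p = 0.470 in camera from limma), with the granule protease gene Ctsg at 6.35 in WT and 7.27 in Merit40-/-, and Hp lower by a difference of -0.40 (SE 0.37). The 14 multipotent progenitor markers averaged 0.11 (adjusted p = 0.319 in camera from limma), with Cd48, the negative marker of the sort, at 5.42 and 5.39 and Cd69 at -0.14. The 29 lymphoid genes averaged -0.01 (adjusted p = 0.929 in camera from limma), with Ighm at 0.54 (SE 0.33) and Nkg7 at -0.69 (SE 0.28), and the 23 dendritic cell and macrophage genes averaged -0.08 (adjusted p = 0.133 in camera from limma), with C1qb at 0.29 and H2-Eb1 at -0.45. The 14 mast cell and basophil genes had a mean just above 0 (0.0034), a median just below it (-0.016) and an adjusted p of 0.985 in camera from limma, with Hdc at 0.40 and Prss34 at -0.27. The 24 stromal and endothelial genes had an adjusted p of 0.959 in camera from limma, whose direction (down) differs from their mean of 0.0023 and median of 0.0095, with Emcn at 0.45 (SE 0.19) and Cxcl12 at -0.59 (SE 0.22). In these 6 lists 0 members passed over all genes and 0 adjusted over the list alone. Without Merit40-/- replicate 3, the granulocyte list (mean 0.22) and the progenitor list (mean 0.20) rose past the threshold in camera and the dendritic cell list fell past it (mean -0.13), as the last also did without WT replicate 3 (mean -0.18). With all arrays these lists had adjusted p = 0.858, 0.781 and 0.776 with an estimated correlation in limma, and their lowest and highest means with 1 array left out were -0.04 and 0.22, 0.02 and 0.20, and -0.18 and 0.0089. Genes of p53 signalling, interferon and inflammation did not pass the test as lists. The 34 p53 target genes averaged -0.04 (adjusted p = 0.270 in camera from limma), with Cdkn1a as their highest member and Btg2 as their lowest. The 38 genes of the type I interferon response averaged -0.03 (adjusted p = 0.564 in camera from limma), with Oas3 at 0.23 and Oas1a at -0.37. The 28 genes of interferon-gamma and antigen presentation averaged 0.05 (adjusted p = 0.521 in camera from limma), with the guanylate-binding protein gene Gbp9 at 0.64 (SE 0.23) and Igtp at -0.18. The 26 genes of NF-kB and inflammation averaged -0.03, with Birc3 at 0.43 (SE 0.16) and Ccl5 at -0.48 (SE 0.40), and the 31 immediate early genes averaged 0.07, with Junb at 0.49 (SE 0.15) and again Btg2 as the lowest member. Their adjusted p values in camera from limma were 0.521 and 0.247. The 26 genes of heat shock and the unfolded protein response averaged -0.12 (adjusted p = 0.262 in camera from limma), with the inducible chaperone gene Hspa1b at -1.17 (SE 0.73) and Creld2 at 0.28. In these 6 lists 0 members passed over all genes and 0 adjusted over the list alone. With 1 array left out, the mean of the immediate early genes ran from 0.0045 to 0.106 and that of the heat shock list from -0.188 to -0.066. The interferon-gamma list ran from 0.0040 to 0.0998 and the p53 targets from -0.062 to 0.011.

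Genes of protein synthesis, metabolism and HSC ageing did not pass the test as lists either. The 37 cytosolic ribosomal protein genes averaged -0.01 (adjusted p = 0.780 in camera from limma), with Rps16 at 0.99 (SE 0.33) and Rps23 at -0.70 (SE 0.23). The 46 genes of oxidative phosphorylation averaged -0.04 and the 31 of glycolysis and the hypoxia response 0.09, each at an adjusted p of 0.247 in camera from limma. Cox7b, of respiratory complex IV, differed by 0.63 (SE 0.22), Cycs by -0.43 (SE 0.31), the glycolytic gene Aldoa by 0.64 (SE 0.42) and the glucose transporter gene Slc2a3 by -0.28 (SE 0.18). In WT, Rps16 (4.36), Cycs (4.32) and Aldoa (4.39) read below the median of all genes (4.93), a mark of low signal. The 26 genes of cholesterol and lipid synthesis averaged 0.01 (adjusted p = 0.805 in camera from limma), with Ebp at 0.39 and Scd1 at -0.55. The 39 genes known to be higher in aged HSCs averaged 0.05 (SE 0.02 between arrays), with 27 higher and 12 lower, at an adjusted p of 0.264 in camera from limma. The array means of the genotypes did not overlap in this list or in the quiescence list, where chance gives 10% per list. With 1 array left out their means ran from 0.045 to 0.070 and from 0.054 to 0.098. Neither list passed with fry (adjusted p = 0.391 for both in limma). Ramp2 stood at 5.44 in WT and 6.04 in Merit40-/-, and the metallothionein gene Mt2 at 7.21 and 6.62. In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. The oxidative phosphorylation list fell past the threshold in camera without WT replicate 3 (mean -0.089) or Merit40-/- replicate 3 (mean -0.094), and averaged 0.02 without WT replicate 2 or Merit40-/- replicate 1, while the glycolysis list rose past it without Merit40-/- replicate 3 (mean 0.11). With all arrays they had adjusted p = 0.858 and 0.776 with an estimated correlation in limma.

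**Figure D4:**
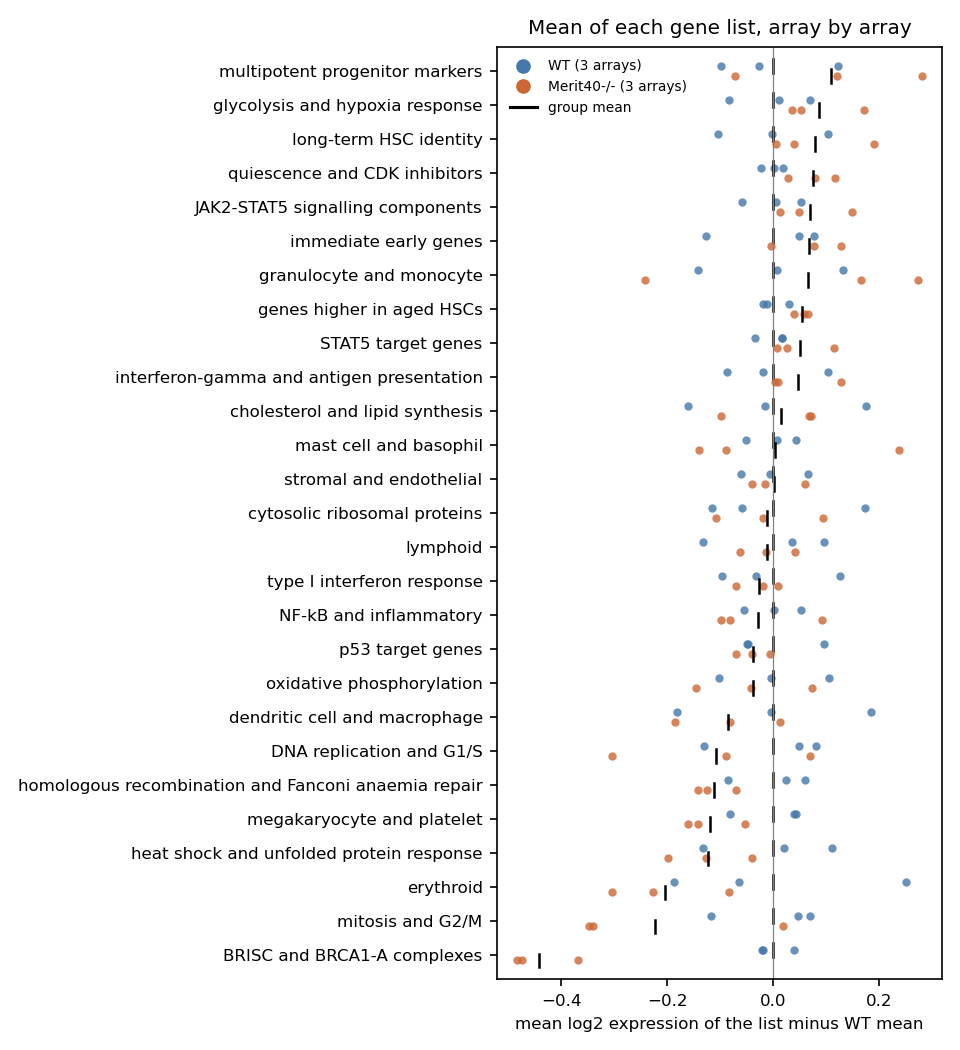
Mean log2 expression of each of the 27 gene lists as the difference from its WT mean (horizontal axis), with WT arrays in blue, Merit40-/- arrays in orange and group means as black bars. The mitosis and G2/M list has a group mean of -0.22 in Merit40-/-, with replicates at -0.34, 0.02 and -0.35. The list of the BRISC and BRCA1-A complexes, which holds Babam1, lies at -0.44.

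The genes next to Babam1 on its chromosome were compared because a targeted allele can carry flanking sequence of another strain. Of the 100 nearest named genes, 50 on each side in the order of assembly GRCm38.p6, 0 passed the threshold in limma and 0 passed adjusted over the list alone. At an unadjusted p under 0.05 there were 5 genes. The median difference was 0.04 and the list's p was 0.530 in camera (0.563 with an estimated correlation). The neighbours with the highest and lowest difference were the microRNA gene Mir28b at 0.65 and Lrrc25 at -0.38, and Hmox1, the gene of haem oxygenase 1, differed by 0.59.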

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

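The settings were chosen before the data were examined, except the list of the complexes without Babam1, which was chosen after seeing the data. Babam1 stayed past the threshold in every setting of the limma test, at differences of -4.06 to -3.85 and adjusted p values of at most 0.00374 in limma. The count of genes was 1 in each of these settings, also over every probe set (25206) and at an adjusted p under 0.1. It was 0 with the unmoderated test, and 207 (115 higher, 92 lower) at an unadjusted p under 0.05 with a difference of at least 0.58. Among the 2021 unnamed probe sets 0 passed in limma, with 80 at an unadjusted p under 0.05. The count of lists, 5 at the preset correlation, was 0 with an estimated correlation (smallest adjusted p = 0.604 in limma) and 1 with fry, the complexes that hold Babam1 (0 without Babam1 in that list). It ranged from 1 to 12 with each array left out: 1 (mitosis) without WT replicate 1 or Merit40-/- replicate 1, 2 without WT replicate 2, 4 without Merit40-/- replicate 2, 8 without WT replicate 3 and 12 without Merit40-/- replicate 3. The cause was not tested, beyond the fewer arrays. Other variance models, weights, scalings and filters on dim genes gave 4 to 7 lists. The HSC identity list passed with 4 of them, at adjusted p values in limma of 0.0397 (trend and robust), 0.0256 (array weights), 0.0461 (quantile) and 0.0365 (cyclic loess), within a range of 0.00221 to 0.868 over all settings of camera at the preset correlation. Over all lists and settings, 394 results stayed on their side of the threshold, 23 lost and 16 gained a call, and 0 calls turned direction. The mean of lists without a call had the other sign in 28 results of 11 lists, so no direction is read from these lists. The dendritic cell list also passed with array weights (adjusted p = 0.0458 in limma). Of the named genes other than Babam1, 0 of 1024 results passed in any setting.

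Arrays with the same replicate number did not deviate together (r = -0.048, -0.003 and 0.044), so the numbers were not taken as pairs. With the replicate block, 1 gene (Babam1, adjusted p = 0.00374 in limma) and the same 5 lists passed, and the neighbours of Babam1 did not. Their median difference, 0.037, was -0.0060 to 0.046 with each array left out, and 0.031 and 0.022 with 25 and 100 neighbours on each side, with 0 calls. A mean over several features of a gene was not run, since each gene has 1 probe set. With 3 arrays per genotype, differences of about 1.5-fold lie mostly below what these data can call, as the simulation gave 12.5% at 0.58.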

Other observations

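The counts of other splits for genes, the late erythroid markers, the 3 tests on G530011O06Rik and Erdr1, the histone family and the small nucleolar RNA family were tests chosen after the results were seen. The quantities measured by the other tests were written down before their values were seen. The muscle and osteoclast tests nevertheless followed from genes that had already stood out. For the mitosis list with an array left out, the reading below also weighs the SE. For the osteoclast genes it also weighs their levels in WT. Both explanations are left open on these added grounds, which are not claimed to have been set beforehand.

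The canonical histone genes, whose transcripts accumulate in S phase, averaged 0.0206 over 35 measured members (14 higher, 21 lower), with a spread of 0.231 (SD, n = 3) between Merit40-/- arrays, so these data do not decide whether fewer cells were in S phase. The 99 small nucleolar RNA genes averaged -0.00417 (SE 0.0646), 49 higher and 50 lower, and the array means of the genotypes overlapped. These values argue against a large shift of the family between the genotypes from carry-over of short RNA. Single arrays ran from -0.11 to 0.07 around the WT mean, so smaller differences between preparations stay open.

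Skeletal muscle transcripts were prominent in Merit40-/- replicate 1 alone. A candidate source is skeletal muscle left on the bones and carried into the marrow preparation, although the double sort for CD150+CD48- LSK cells would remove muscle cells. In 30 other muscle genes listed before their values were seen, none of them in the fixed lists, the mean of this array lay 0.699 above the highest of the other 5 arrays. Ttn, Neb, Myot and Casq1 among them also belong to the 18 genes that stand apart there; without these 4 the mean lay 0.436 above, short of the 0.5 set beforehand for the full list, and 14 of the remaining 26 were highest in this array (4.33 by chance), such as Ampd1 at 6.09. An effect of the genotype on the 30 genes would call for high values in all Merit40-/- arrays, but replicates 2 and 3 averaged 0.02 and 0.09 above the WT mean. Among the muscle genes seen first, Tnnt3 (6.38 and 6.03, at most 5.52 in WT) and Pvalb (4.71 and 4.74, at most 4.59 in WT) exceeded each WT array in both replicates. Tnnc2 (5.27 and 5.62, at most 5.88 in WT) and Tnni2 (5.54 and 5.30, at most 6.20 in WT) did so in neither. For Ctsk and Acp5 in Merit40-/- replicate 3 the same kind of test gave 0.0903, with 4 of the 14 osteoclast genes highest in this array (2.33 by chance). Among them Atp6v0d2 read 4.05 against at most 2.88 elsewhere, while Calcr was lowest in this array at 3.51. That leaves RNA of osteoclasts open, since 8 of the 14 osteoclast genes stood above the median level of all genes in WT HSCs, where a small share would be hidden, although the double sort would remove osteoclasts too.

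The mitosis list was lower in 2 of the 3 Merit40-/- arrays, and a shift of the genotype, cell composition and single arrays are candidate explanations. Array scaling stays open: the mean difference was -0.212 or lower under 3 other scalings, but these moved the differences of genes by a median of at most 0.0114 and so test little. A decision by 1 array also stays open: without Merit40-/- replicate 3 the mean was -0.160 (SE 0.154), and without Merit40-/- replicate 1, the array with muscle transcripts, it was -0.164. Fewer erythroid cells in the Merit40-/- sorts also stay open, with 9 late erythroid genes at a mean difference of -0.204 against a pooled SD of 0.350, although the double sort for LSK cells would remove late erythroid cells. Chance could not be excluded for the lists. Of the 10 splits of the 6 arrays, the real one included, 6 gave at least as many lists as the real 5. Another split gave up to 9, and 4 of the 10, again with the real one, called the mitosis list. The other splits mix the genotypes, so they can carry part of a genotype effect.

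G530011O06Rik, Erdr1 and Mid1 lie near the end of the X chromosome in assembly GRCm38.p6. All 3 had lower means in Merit40-/- (-2.25, -1.20 and -0.53), short of the threshold. Flanking sequence around the targeted allele does not account for this, as 0 of the first 2 lie on the chromosome of Babam1. Their mean was -1.71 or lower under the 3 other scalings, which moved too little to test array scaling. A sequence or copy number difference between the mice in this region, next to the pseudoautosomal boundary, may underlie it and cannot be tested without genotypes, and an effect of Merit40 loss was not tested further. The 10 nearest named X-linked genes averaged 0.0238, and only 1 of them, Mid1, picked after its value was seen, had an unadjusted p under 0.05 in limma. 4933400A11Rik (-0.07, SE 0.18) and Asmt (0.10, SE 0.14), which come before Mid1 in order of distance, showed no clear difference. The levels of 4933400A11Rik and Asmt were not weighed, and a gene of low signal may not show a fall. Whether the lower genes form 1 continuous stretch is therefore not decided.

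For the count of genes, 1 of the 10 splits gave as many as the real 1, with 0 as the highest other count, and 10 splits are too few for a share under 0.05. Of the 100 neighbours of Babam1, 5% had an unadjusted p under 0.05 against a median of 4% in random sets of genes and 9% at the upper end of their central 95%, so flanking sequence of another strain is neither shown nor excluded. Of the 10 splits, 6, the real one included, gave the neighbours a camera p at least as small as the real 0.530, with 0.0791 as the smallest.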
